A study of Mus musculus with 2 samples.

How the data were processed

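Total RNA from LPC-HRas mouse liver tumour cells infected with lentivirus carrying shRFP or shETV4 was made into libraries with an Illumina TruSeq kit, per the labels' protocols. There were 2 libraries, 1 per group, and the group of each was taken from its treatment label. The value columns' names end in _2, and whether that marks a further run or replicate is not given in the sources used here. The deposited values are TPM made by the authors, 1 value per gene and library with 2 decimals; the unit was read from the values, since the totals of 999999.77 for shRFP and 999870.3 for shETV4 are those of TPM and the headers name no unit; why the latter total is short is unknown. HISAT2, RSEM and the genome build GRCm38.p4 are named, without roles or versions, in the submitters' processing notes. The assembler, annotation release, strand setting and any filters are not given in the sources used here. TPM divides by transcript length and by the library's own total, so a large gain in some RNAs lowers the values of all others, and depth cannot be recovered from it. No counting interval or floor is therefore given, and a value of 0 is described as listed at 0.

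Both files held 55640 records, of which 55487 had a gene symbol and 153 had only an assembler's locus number. The unnamed loci stayed out of all counts and lists; they held 1.13% of the TPM with shRFP and 2.67% with shETV4. Gene symbols are those of the files, and GENCODE M21 on GRCm38, which covered 99.4% of the named records by gene identifier, gave biotype, coordinates, transcript length and GC content (medians over a gene's transcripts) and the share of exonic bases lying in exons of another gene on either strand. Older symbols on the lists were matched through RefSeq synonyms, after which every listed gene was found. Overlapping genes, paralogs and repeated small RNAs were kept, since the way reads were divided among them is unknown.

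The difference of a gene was log2(shETV4 TPM + 1) - log2(shRFP TPM + 1), with a pseudocount of 1. A gene was evaluated, or measured, when it reached 1 TPM in at least 1 library and was called higher or lower at a difference of 1 or -1. With 1 library per group no p-value, standard error or replicate comparison could be given. For each of 37 gene lists the median difference of the evaluated members was placed among 10000 random lists of the same size drawn from 20 bins of mean level, and a list was said to stand apart at or below percentile 2.5 or at or above 97.5. This describes these libraries and tests nothing; 1.85 lists would stand apart by chance, and 13 did, 8 high and 5 low. The lists, thresholds and the rule for naming genes were fixed before the data were examined. The rule names Etv4, Etv1 and Etv5, then the 12 genes with the largest difference in each direction among those at 5 TPM or more in either library, passing over predicted and clone-named genes. From each list it takes up to 4 members in each direction and up to 4 more where the list stands apart. Genes named outside it (Hras, Myc, the immune, hepatocyte and reference genes given at their levels, Acta2, the members past 2-fold only after GC adjustment and the members given only as going against their list) were chosen after their values were seen, as were the protein-coding repeat of the rule and 4 further lists in the closing section.

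Alternatives fixed beforehand changed the pseudocount (0.1, 5), the filter (none, 5 TPM), the scale (median ratio of genes at 5 TPM or more in both set to 1; a trimmed mean of log ratios, trimming 30% of ratios and 5% of means at each end), the threshold (1.5-fold, 3-fold), the gene set (protein-coding), the matching of random lists and the use of the mean in place of the median. After the data were seen, a GC adjustment was added that subtracts the running median of the difference over 50 bins of GC content, and random lists drawn within 4 bins of level, 10 of GC content and 4 of length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with BLAST+ 2.17.0 for a search of transcripts against gene models of the ribosomal RNA repeat (at least 50 bases at 90% identity). The procedure was tested on simulated data for the shETV4 against shRFP comparison with 12572 genes and an assumed noise SD of 0.2 on the log2 scale, 50 genes for each planted fold. It called 4% of genes planted at 1.5-fold, 96% at 3-fold, 100% at 4-fold and at 8-fold and 0% of unchanged genes, placed a list raised by 0.5 at percentile 100, and set 4% of 200 lists without a planted change apart. The simulated rank correlation with GC content was 0.66 before and 0.01 after adjustment. Noise was drawn independently for each gene and library, calls were simulated without a GC trend, and genes listed at 0 with shRFP stayed there. The real differences had an SD of 0.51 among genes at 5 TPM or more in both libraries. The simulated rates are therefore not error rates of the real comparison.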

Results

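RNA sequencing was carried out on LPC-HRas cells, a mouse liver tumour cell line, infected with lentivirus that carried either the control hairpin shRFP or a hairpin against Etv4, shETV4. There was 1 library per group, so no difference below has a replicate check and none was tested; all statements describe these 2 libraries. Values are TPM, transcript abundances scaled to length and to the total of each library, which keep no record of sequencing depth, so the depth of each library and the counting error behind each value are unknown. At 1 TPM or more there were 12456 named genes in the shRFP library and 12281 in the shETV4 library. Differences are log2(TPM + 1) in shETV4 minus log2(TPM + 1) in shRFP, a scale that understates the difference of genes at low level, and a gene was called higher or lower when it differed at least 2-fold on that scale. Fold values given beside TPM levels are plain ratios of the TPM.

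The comparison asks how gene expression differs in these cells when the hairpin against Etv4 replaces the control hairpin. Etv4 itself, an ETS-family transcription factor of the PEA3 group, was 4.52-fold lower in the shETV4 library. Among the 37 gene lists, the widest shared difference ran the other way: genes of the interferon response and of antigen presentation were higher. Of their measured members 18 of 25 and 7 of 13 were called higher and none lower. Lower in the shETV4 library were groups of G2/M genes and YAP target genes and, against level-matched lists, ribosome synthesis and MYC target genes. Output genes of the RAS-MAPK pathway, which HRas drives, had a median near 0.

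Etv4 (ENSMUSG00000017724) lies on chromosome 11 at 101769742 to 101785371 on the minus strand of GRCm38, and none of its exonic bases lie in exons of another gene. Its level was 73.2 TPM with shRFP and 16.2 TPM with shETV4, a difference of -2.11. Among 9375 named protein-coding genes at 5 TPM or more in either library it had the rank 21 from the lowest difference, and the rank 8 after adjustment for GC content. Etv1 (ENSMUSG00000004151, chromosome 12, 38779380 to 38870484, plus strand), another PEA3 factor, was at 18.5 and 20.8 TPM. Etv5 (ENSMUSG00000013089, chromosome 16, 22381309 to 22439719, minus strand), the remaining member, was at 33.2 and 46.6 TPM. These other PEA3 genes thus lay within 2-fold, at a median difference of 0.32 (percentile 91.3 of random lists). Hras was at 67.7 and 68.8 TPM.

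All 25 genes of the interferon response list were measured, and their median difference was 1.40. That placed the list at percentile 100 of 10000 random lists of the same size matched on expression level, and at percentile 100 again with matching on GC content and transcript length as well. Irf7, the transcription factor that amplifies interferon production, was at 20.4 TPM with shRFP and 125 TPM with shETV4, or 6.11-fold higher. Ifit3, an interferon-induced antiviral protein, went from 32.6 to 180 TPM between the libraries, 5.50-fold. The oligoadenylate synthetase genes Oas2, Oasl2 and Oas1a were 7.41-fold, 4.45-fold and 4.54-fold higher, reaching 11.1, 194 and 66.7 TPM with shETV4. With shRFP they were at 1.5, 43.7 and 14.7 TPM. The antiviral GTPase genes Mx1 and Mx2 were at 0.69 and 3.85 TPM with shRFP and at 4.72 and 18.8 TPM with shETV4. Rsad2, which encodes viperin, was 4.06-fold higher, at 39.5 TPM. The 7 members within 2-fold included Ifit2, the list's only member below 0, at 10.4 and 8.49 TPM. Ifit, Oas and Mx genes have close relatives, and how reads were divided among them is not given in the sources used here.

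Antigen presentation genes differed in the same direction. All 13 were measured, 7 were called higher and 6 lay within 2-fold, with a median difference of 1.30 at percentile 100 under both ways of matching. Psmb9 and Psmb8, subunits of the immunoproteasome, were 7.76-fold and 2.86-fold higher, at 8.85 and 55.2 TPM with shETV4. With shRFP they were at 1.14 and 19.3 TPM, so the ratio of Psmb9 rests on a low control level. Tap1, part of the peptide transporter of the endoplasmic reticulum, was at 6.35 and 29.4 TPM, 4.63-fold higher. The class I heavy chain genes H2-K1, H2-D1 and H2-T23 were 2.77-fold, 2.48-fold and 2.65-fold higher; these are near-identical in parts, so the division of reads among them is uncertain. Nlrc5, the transactivator of class I genes, was at 3.08 and 9.91 TPM. Erap1, which trims peptides, was the only member below 0, at 8.51 and 5.30 TPM. Leukocyte markers stayed low in both libraries: 2 of 16 immune cell genes reached 1 TPM, Cd14 at 8.68 and 15.2 TPM and Cd68 at up to 1.98 TPM, with a list median of 0.66 (percentile 95.1). Ptprc was at 0 and 0.03 TPM and Lyz2 at 0.06 and 0.11 TPM. The single endothelial marker measured of 12, Egfl7, was at 13.5 and 18.8 TPM, a difference of 0.45 (percentile 89.9).

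**Figure D1:**
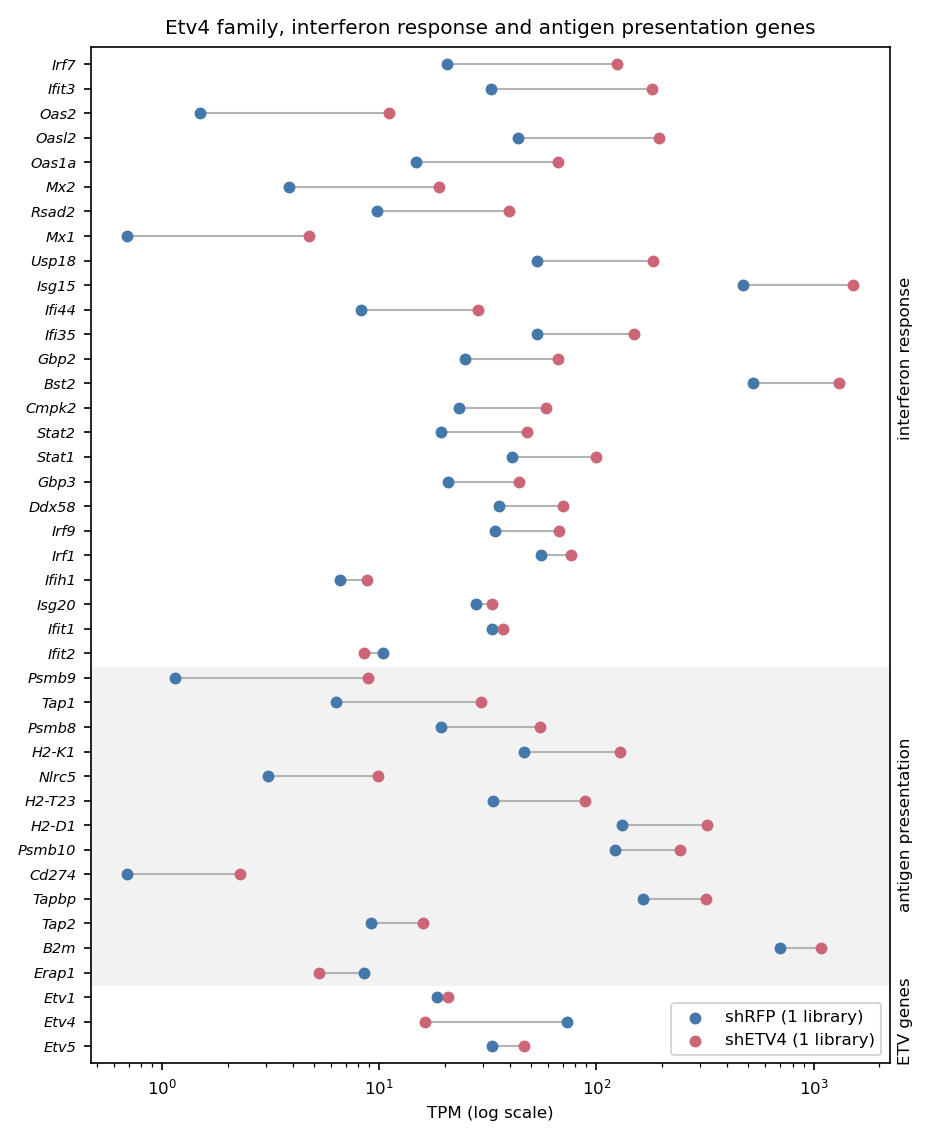
TPM of each measured interferon response and antigen presentation gene and of Etv1, Etv4 and Etv5 in the shRFP library (blue) and the shETV4 library (red), 1 library each, on a logarithmic axis. Etv4 lies at 73.2 and 16.2 TPM, and 18 of 25 interferon response genes and 7 of 13 antigen presentation genes were called higher with shETV4.

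Of 12968 genes at 1 TPM or more in at least 1 library, 439 were called higher and 916 lower in the shETV4 library. Among the 11561 protein-coding genes the counts were 247 and 736. The excess of lower genes followed base composition. Genes called lower had a median transcript GC content of 43.6%, against 52.7% for genes called higher and 50.7% for all, and the rank correlation of the difference with GC content was 0.52 across 12947 genes, which are not independent replicates. Among the 1295 genes with the lowest GC content, 377 were called lower and 25 higher, while among the 1295 with the highest, 28 were called lower and 62 higher. With the running median over GC content subtracted, 516 genes were called higher and 299 lower; 382 of the higher genes and 278 of the lower genes were called both with and without the adjustment. Of the gene list members within 2-fold, 9 came past it upward with the adjustment (Irf9, Ddx58, B2m, Cd274, Cxcl2, Cxcl16, Itga1, Dcn and Pparg) and none downward. The deposited scale also mattered for the balance: the trimmed mean of log ratios lay at -0.13, and dividing it out gave 546 higher and 655 lower. Differences below are on the deposited scale. Of the lower genes named below, Tjp1, Esrp2, Tagln, Timp3, Elovl6, Scd2, Hsp90b1 and F3 came inside 2-fold on the trimmed-mean scale, as did Tagln, Timp3, Scd2 and Hsp90b1 with the median ratio set to 1.

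**Figure D2:**
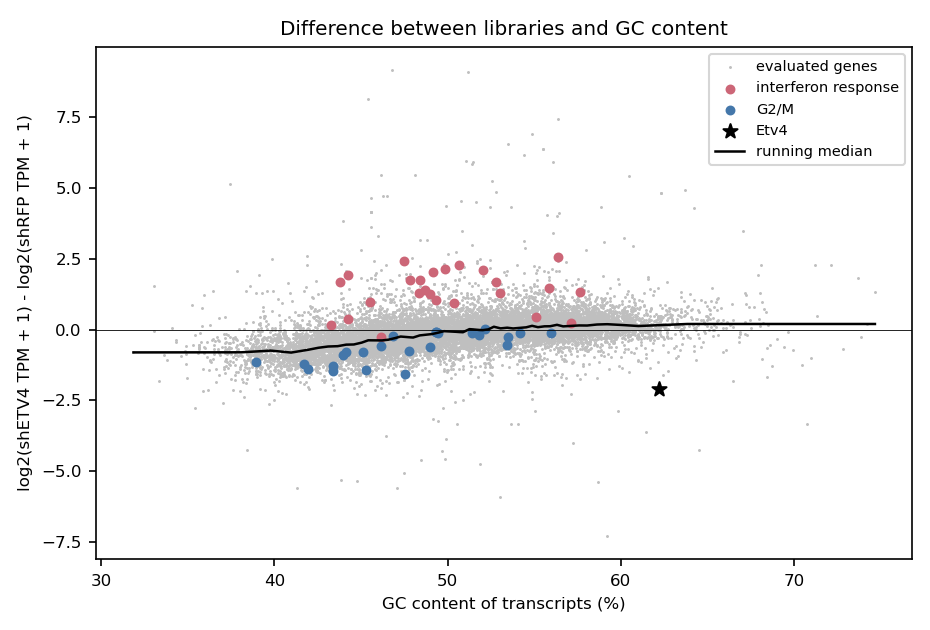
Difference between the libraries, log2(shETV4 TPM + 1) - log2(shRFP TPM + 1), against the GC content of each evaluated gene's transcripts in percent; the line is the running median, and coloured points are interferon response genes (red), G2/M genes (blue) and Etv4 (star). The median was -0.74 over the 1295 genes lowest in GC content and 0.17 over the 1295 highest, and most interferon response genes lay above the line.

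Of the 12 named genes with the largest difference upward, 10 were non-coding, most of them small structural RNAs. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, carried the same values of 19.2 and 570 TPM in the files, 29.6-fold higher with shETV4, so the division of reads between the copies is undefined; their class, misc_RNA, had 5 of 16 measured genes called higher and 9 lower. The 2 annotated records of Rmrp, the RNA of an RNA-processing ribonuclease, were at 10.5 and 222 TPM and at 0 and 29.5 TPM. Snora64, Snora5c, Rnu3a and Mir1949, annotated as snoRNAs that overlap exons of other genes, and the spliceosomal RNAs Rnu12 and Rnu2-10 were all listed at 0 with shRFP and between 16.8 TPM (Rnu2-10) and 61.0 TPM (Mir1949) with shETV4. The protein-coding genes among them were Zfp618, a zinc finger gene at 0.55 and 26.1 TPM, and Pagr1a at 0.37 and 26.2 TPM, of whose exonic bases 98.7% lie in exons of another gene. Downward, the snoRNAs Snora17, Snora34 and Snora16a were at 58.4, 47.2 and 46.7 TPM with shRFP and were listed at 0 with shETV4. Snora16a shares all of its exonic bases with another gene and Snora34 66.7% of them, while Snora17 shares none. Ndufa5, a subunit of respiratory complex I, was at 151 and 21.1 TPM, or 7.16-fold lower. Prr14l was at 15.1 and 0.11 TPM, Npas3 at 10.7 and 0.17 TPM, Swt1 at 8.65 and 0.71 TPM, Gstp2 at 7.65 and 0.58 TPM, Suco at 15.1 and 2.10 TPM and Rps6ka6 at 11.4 and 1.46 TPM. Snurf and the second record of Arhgef4, at 26.0 and 9.05 TPM with shRFP and listed at 0 with shETV4, share all of their exonic bases with another gene.

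The same rule was applied to protein-coding genes alone, a repeat chosen after these values were seen. Upward it named Pagr1a and Zfp618 again and 3 genes of the interferon response list, Irf7, Ifit3 and Oas2. Zbp1, a sensor of Z-form nucleic acid, was at 6.38 and 57.6 TPM, 9.03-fold higher. Igtp, an interferon-inducible GTPase gene, was 5.27-fold higher at 67.9 TPM, and Ifit3b was 5.87-fold higher at 42.9 TPM. Col15a1, a basement membrane collagen gene, was at 3.41 and 22.8 TPM. Hist1h4m, Cldn34c2 and Fam220a were at 12.4, 6.94 and 12.6 TPM with shETV4, from 0.73, 0.31 and 1.43 TPM with shRFP. At the lower end the repeat added Dnajc12 at 11.4 and 1.57 TPM, and Hmgn5 and the chromatin remodeller Atrx at 28.6 and 29.3 TPM with shRFP and 5.16 and 5.43 TPM with shETV4, the latter pair with a GC content of 40.7% and 40.5%.

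Genes of the G2/M phase were lower as a group. None of 24 was called higher and 7 were called lower, and the median difference was -0.59, at percentile 0 of level-matched lists and 0.02 with GC content and length matched too. Mki67, the proliferation marker, was at 34.95 and 11.24 TPM, or 3.11-fold lower. Top2a, a topoisomerase of dividing cells, was at 174 and 62.5 TPM, and Cenpf, a centromere protein gene, at 7.29 and 2.05 TPM. Hmmr, Ttk, Kif11 and Bub1 were 2.86-fold, 2.77-fold, 2.43-fold and 2.40-fold lower. Most of these genes are poor in GC, and after adjustment for it Mki67 (-1.30) and Cenpf (-1.04) were still past 2-fold while the other 5 were not, with a list median of -0.33. With pseudocount 5, Cenpf, Ttk, Kif11 and Bub1 came inside 2-fold, while Mki67, Top2a and Hmmr stayed past it. Aurkb, at 90.8 and 93.2 TPM, was the only member above 0. The G1/S list did not stand apart, with 1 of 24 genes called lower, Ccne2 at 11.5 and 4.32 TPM (-0.56 after GC adjustment), and a median of -0.13 (percentile 12.2). Among 20 measured p53 targets and cell cycle inhibitors, Cdkn1a, which encodes p21, was called higher at 2.25 and 11.9 TPM, 5.29-fold, and 19 lay within 2-fold. That list's median was 0.18 at percentile 99.3 (99.2 with GC content and length matched; 93.6 by the mean), although Mdm2 and Ccng1, at 21.4 and 10.1 TPM with shRFP, were at 14.5 and 5.36 TPM with shETV4.

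Of 24 genes of ribosome synthesis and MYC targets, 5 were called lower and none higher, and 22 lay below 0. The median was -0.30, at percentile 0.04 and, with GC content and length matched, 0.03, but 6.43 against random lists without matching, inside the central range. Odc1, the first enzyme of polyamine synthesis, was at 270 and 66.9 TPM, or 4.04-fold lower. The nucleolar protein genes Ncl, Npm1, Nop58 and Wdr43 were 2.60-fold, 2.36-fold, 2.27-fold and 2.28-fold lower, with Npm1 at 1399 and 592 TPM; after GC adjustment Odc1 alone of the 5 was past 2-fold, at -1.72. Myc itself was at 280 and 264 TPM. Ribosomal protein genes did not stand apart: all 24 lay within 2-fold, with a median of 0.03 (percentile 71.1).

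YAP target genes were lower too, with 16 of 18 below 0, 3 called lower and a median of -0.48 at percentile 0.12 (0 with GC content and length matched). Ankrd1, a cardiac-type ankyrin repeat gene widely used as a YAP readout, was at 152 and 50.2 TPM, 3.04-fold lower. Crim1 and F3, the latter encoding tissue factor, were 2.73-fold and 2.17-fold lower, though F3 was at -0.82 after GC adjustment. Ccn2 and Ccn1, known earlier as Ctgf and Cyr61, were at 31.3 and 238 TPM with shRFP and at 16.5 and 137 TPM with shETV4, within 2-fold. Axl, at 212 and 245 TPM, had the highest difference of the list. Among 20 TGF-beta targets, Tgfb2 and Inhba were called lower, at 7.2 and 2.33 TPM and at 4.63 and 1.3 TPM, Inhba being just inside 2-fold after GC adjustment; the list median was -0.02 (percentile 74.3).

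Only 8 of 20 genes of epithelial junctions and keratins were measured, and their median was -0.69 at percentile 0.4 (0 with GC content and length matched). Their mean was -0.45 at percentile 7.1, inside the central range. Tjp1, a tight junction scaffold, was at 30.3 and 13.6 TPM and Esrp2, an epithelial splicing factor, at 2.12 and 0.53 TPM, both called lower, Tjp1 being at -0.77 after GC adjustment; Cdh1 was at 4.73 and 4.71 TPM and Krt19 at 27.5 and 36.3 TPM. The mesenchymal and matrix list went both ways, its median of 0.16 (percentile 98.9; 99.4 with GC content and length matched; 96.3 with pseudocount 5) and its mean of -0.11 (percentile 36.3) differing in sign. Lox, a collagen cross-linking enzyme, was 3.74-fold lower at 22.6 and 6.04 TPM and Tagln, a smooth muscle actin-binding protein gene, 2.01-fold lower at 314 and 156 TPM, with 67.9% of its exonic bases shared with another gene and a call lost with pseudocount 5 and on both other scales; the other 20 of 22 lay within 2-fold. Acta2, smooth muscle actin, was at 1256 and 655 TPM, and Twist2 and Col3a1 were at 59.7 and 538 TPM with shETV4, from 38.8 and 368 TPM. All 8 measured genes of 15 on the stellate cell and fibroblast list lay within 2-fold, with a median of 0.35 at percentile 99.5 (99.8 with GC content and length matched; 92.7 by the mean), Col3a1 among them. Timp3, a metalloprotease inhibitor, at 90.8 and 43.3 TPM and -0.96 after GC adjustment, was the 1 called gene of 13 proteases and inhibitors (median 0.17, percentile 96.4). Itga3, at 63.7 and 28.6 TPM, was the 1 called gene of 9 integrins (median 0.06, percentile 74.9).

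Genes reported as PEA3-family targets had no shared large difference. Of 14 measured, Met, the hepatocyte growth factor receptor, was called lower at 19.8 and 6.07 TPM, 3.27-fold, and Ccnd3, a D-type cyclin, higher at 136 and 304 TPM, 2.24-fold and 0.98 after GC adjustment. The other 12 lay within 2-fold, among them Mmp2 at 206 and 317 TPM and Ptgs2 at 7.71 and 4.28 TPM, Cd274 passing 2-fold after GC adjustment (1.44), and the median was 0.20 at percentile 98.8 (99.5 with GC content and length matched; 88.8 by the mean; 97.0 at 5 TPM or more). RAS-MAPK output did not stand apart, with 1 of 21 genes called higher, Areg at 0.57 and 3.51 TPM, and 1 lower, Epha4 at 4.44 and 1.07 TPM. The median there was 0.08 (percentile 92.4), with the feedback gene Spry4 at 6.05 and 10.6 TPM and Egr1 at 16.8 and 34.1 TPM. Receptor tyrosine kinases and their ligands had Met and Areg as their only called genes of 23, with a median of 0.08 (percentile 94.2). The immediate early and stress list had a median of 0.30 at percentile 99.96 (99.1 with GC content and length matched; 96.7 by the mean), yet its 1 called gene of 21 was lower: Hsp90aa1, a heat-shock chaperone, at 212 and 52.0 TPM, 4.07-fold. Egr1, Hspa1a and Egr3 were the highest of it, at differences of 0.98, 0.85 and 0.68.

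Few markers of hepatocytes were measured in either library. Of 24, 4 reached 1 TPM, and the albumin gene Alb was listed at 0 in both; Trf, the transferrin gene, was called higher at 27.5 and 127 TPM, with 63.5% of its exonic bases shared with another gene (list median 0.52, percentile 97.4). Of 13 measured progenitor, fetal liver and biliary genes Cd24a was called lower, at 132 and 55.5 TPM, and 12 lay within 2-fold, Sox9 and H19 among them at differences of 0.68 and 0.62 (median 0.08, percentile 84.4). NF-kB targets had 2 of 16 called higher, Saa3, an acute phase protein gene, at 115 and 337 TPM and Lcn2, lipocalin 2, at 11.7 and 27.1 TPM. Their median of 0.23 stood at percentile 99.3, but at 97.2 with GC content and length matched and 94.8 at 5 TPM or more, inside the central range. Of 18 chemokines and cytokines, Ccl5, a T-cell attractant, was called higher at 164 and 441 TPM and Il6 had the lowest difference, at 5.24 and 2.46 TPM (median -0.15, percentile 29.4). That unadjusted median stood at percentile 82.9 with GC content and length matched. After GC adjustment the median of the list was 0.41, and Cxcl2 and Cxcl16 were called higher besides Ccl5. Cxcl16 was at 6.47 and 13.85 TPM, but Cxcl2 was close to the 1 TPM filter, at 0.52 and 1.25 TPM.

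In lipid metabolism, Acly, Elovl6 and Scd2, enzymes of fatty acid synthesis, were called lower at 232 and 92.8 TPM, 26.2 and 11.8 TPM, and 838 and 403 TPM; the list of 20 had a median of -0.02 (percentile 57.7). Idi1 and Sc5d were called lower among 20 sterol synthesis genes (median -0.01, percentile 50.02), at 55.2 and 16.9 TPM and at 48.7 and 21.4 TPM. Nqo1, a quinone reductase, was the 1 called gene of 19 NRF2 targets, at 21.2 and 44.5 TPM (median 0.06, percentile 82.3). Hsp90b1 was the 1 called gene of 24 in unfolded protein and amino acid stress, at 213 and 102 TPM (median -0.03, percentile 56.9), and Xiap the 1 of 17 apoptosis regulators, at 14.2 and 5.75 TPM (median 0.01, percentile 80.8). Of these lower genes Acly stayed past 2-fold after GC adjustment, at -1.30, whereas Elovl6, Scd2, Idi1, Sc5d, Hsp90b1 and Xiap did not. Dkk1, a secreted Wnt antagonist, was the 1 called gene of 8 Wnt targets, at 1.13 and 7.43 TPM (median -0.12, percentile 49.3). The replication histone genes H1f2 and H3c13 were called higher among 10 (median 0.15, percentile 91.1), H1f2 at 0.94 after GC adjustment and the latter sharing all its exonic bases with another gene. No gene was called in glycolysis and hypoxia (24 genes, median 0.06, percentile 86.2), oxidative phosphorylation (22 genes, median -0.01, percentile 51.7), Notch targets (8 genes, median 0.08, percentile 85.5) or common reference genes (12 genes, median -0.07, percentile 28.8), though B2m was at 1.42 after GC adjustment. Reference genes were not all level: Actb was at 4603 and 2930 TPM and Gapdh at 6735 and 6954 TPM. The 13 mitochondrially coded genes, all within 2-fold, had a median of -0.43 at percentile 0; the percentile was 64.3 with GC content and length matched and 4.1 against random lists without matching.

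**Figure D3:**
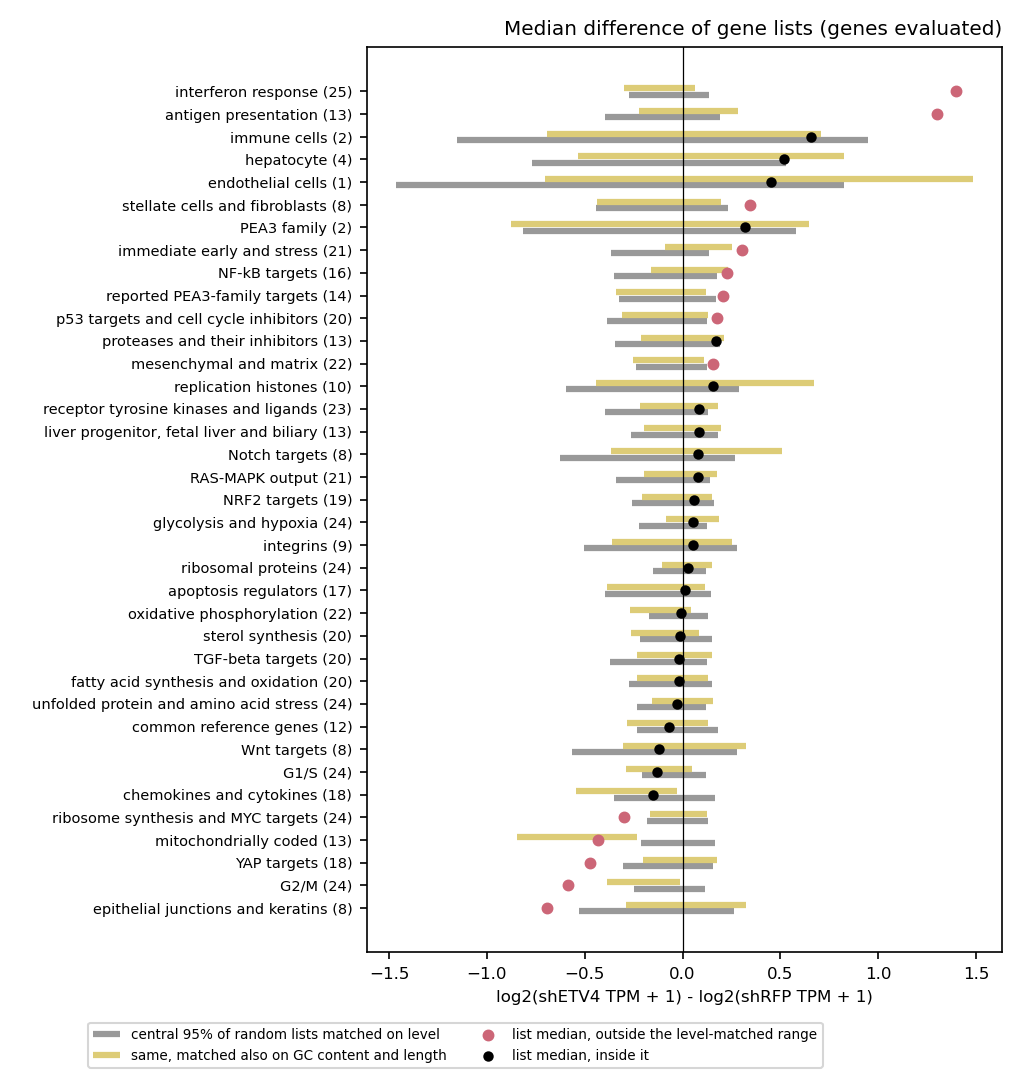
Median difference, log2(shETV4 TPM + 1) - log2(shRFP TPM + 1), of each gene list (points; the number of measured genes is in parentheses), with the central 95% of 10000 random lists matched on level (grey) or on level, GC content and length (yellow). Red points lie outside the grey range; 13 of 37 lists did so, with interferon response at 1.40 and epithelial junctions at -0.69 as the extremes of the medians; by the mean the latter list was at percentile 7.1.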

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

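All tests in this part were chosen after the result was seen. Loci without a gene name, which enter no comparison, held 2.67% of the TPM in the shETV4 library against 1.13% in the control library. The gain lay in few loci: 7 at 1000 TPM or more in either library together had 8891 TPM with shRFP and 24488 TPM with shETV4, with ratios from 2.12 to 3.15. Of 123 unnamed loci above 0 in both libraries, 23 were at least 2-fold higher and 19 at least 2-fold lower, so the loci below that level went both ways.

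Structural RNA genes (snRNA, snoRNA, scaRNA and ribozymes) were higher as well, with 43 of 52 measured called higher and 4 lower, and snRNA genes alone 18 of 18 higher (median 4.33). The misc_RNA class as a whole did not share this, with 5 of 16 called higher, Rn7s1 and Rn7s2 among them, and 9 lower (median -1.32). Nor did miRNA genes, with 4 of 10 higher and 3 lower. Unstable TPM of short features, which should scatter both ways, stays open: over all 6 classes 76.5% of the called genes were higher, neither near an even split nor nearly all. The snRNA genes have 5 transcript lengths and 13 pairs of values among them, as repeated copies that share reads would, so the 18 are not independent features; 15 were listed at 0 with shRFP. For the unnamed loci, more ribosomal RNA in the shETV4 library may be a source. The gene models of the ribosomal RNA repeat were the targets of the search, so they could not themselves be counted as matches. The 1 measured gene found to match them, CT010467.1, is itself annotated as ribosomal RNA, the only measured gene of the biotype rRNA. It was at 2173 and 5558 TPM, a difference of 1.35 and a ratio of 2.56, so this record was higher with shETV4. With 1 such gene, whose biotype had already been summarised when the test was set up, and with no sequence for the loci, the source of the unnamed loci cannot be settled. Whether these RNAs differ through Etv4 or through library preparation was not tested.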

How the results depend on the processing

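With 1 library per group and unknown depth, no biological or counting error can be set beside these values, and no paired or leave-out analysis was possible because each group has 1 library. The alternative on counts was not run, as only TPM were analysed here. Etv4 stayed lower under all alternatives, from -1.88 (pseudocount 5) to -2.27 (GC-adjusted). Genes called higher and lower numbered 674 and 1459 with pseudocount 0.1 and 167 and 267 with pseudocount 5. At 1.5-fold they numbered 1117 and 2591, and at 3-fold 162 and 162. The thresholds and pseudocounts change the totals by construction. The balance changed too: at 3-fold the counts were equal, so the excess of lower genes lay in differences short of 3-fold. The higher count was 252 at 5 TPM or more and 247 among protein-coding genes, both from fewer genes. The lower count was 299 with GC adjustment and 177 when also limited to protein-coding genes, alternatives chosen after seeing the data. Of the 13 lists that stood apart, interferon response, antigen presentation, G2/M and YAP targets did so under every alternative run for lists. Of the other lists, hepatocyte genes (4 measured) came outside the central range with pseudocount 0.1, unmatched, by the mean and at 5 TPM or more, where Trf alone was left, and proteases with pseudocount 5. Percentiles came inside the central range with the mean in place of the median for reported PEA3-family targets (88.8), p53 targets (93.6), epithelial junctions (7.1), mesenchymal and matrix (36.3), stellate cells (92.7) and immediate early genes (96.7). At 5 TPM or more the PEA3 targets were at 97.0 and NF-kB targets at 94.8, and with pseudocount 5 the mesenchymal list was at 96.3. Against unmatched random lists, ribosome synthesis and MYC targets were at 6.43 and mitochondrially coded genes at 4.1. With GC content and length matched, NF-kB targets were at 97.2 and mitochondrially coded genes at 64.3. Except as stated, the cause was not tested. Among called genes that the text may name, 54 higher genes stayed past 2-fold with GC adjustment and 2 did not, and 35 lower genes stayed and 20 did not, while 9 list members within 2-fold came past it upward and none downward; with pseudocount 5, 8 higher and 15 lower genes came inside 2-fold. With the trimmed-mean scale 8 lower genes did so and with the median ratio 4, and no higher gene. No call reversed.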

Other observations

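All lists and tests in this part were chosen after the values were seen, so the percentiles describe and are not independent evidence. The lists also reuse genes of the fixed lists. These are Gbp2 and Gbp3 among the GTPases and Tagln, Acta2 and Actb among the contractile genes. Among the plasma proteins they are Trf, Saa3 and Lcn2, all called higher above. Immunity-related and guanylate-binding GTPases, interferon-inducible genes of defence inside the cell, were higher throughout: 14 of 14 measured lay above 0 and 7 were called higher, with a median of 1.02 at percentile 100 under both ways of matching. Igtp, Irgm2 and Ifi47 were 5.27-fold, 5.19-fold and 3.28-fold higher, and Gbp2 and Gbp6 2.70-fold and 2.33-fold. The positions of Igtp and Irgm2 overlap on the plus strand of chromosome 11. They share 8.01% and 4.39% of their exonic bases with another gene, and Gbp6 shares 29.0%. How reads were divided among such genes is unknown, so they may not be separate observations. Secreted plasma and acute phase proteins were higher as well, in 7 of 11 measured genes (median 1.14, percentile 100): Agt, angiotensinogen, at 11.2 and 50.3 TPM, Serpina3n at 1.26 and 5 TPM and complement C3 at 5.74 and 15.4 TPM. The interferon gene Ifnb1 was listed at 0 with shRFP and at 0.68 TPM with shETV4, below the 1 TPM needed to be measured, so no difference is read from it.

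Contractile genes and targets of serum response factor lay lower together, 19 of 20 below 0 and 3 called lower, with a median of -0.59 at percentile 0 under both ways of matching. Cnn1, calponin, was at 11.8 and 1.77 TPM and Myl9, a myosin light chain gene, at 54.4 and 17.7 TPM. Actg1 and Tpm1, far more abundant, were at 4884 and 2224 TPM with shRFP and at 2804 and 1202 TPM with shETV4. Srf itself was at 63.5 and 45.2 TPM. Members of the YAP list are regulated in part by the same cytoskeletal signals; no test here separates the groups.

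The higher interferon and antigen presentation genes do not follow the GC trend, since the interferon list stood at percentile 100 among lists matched on level, GC content and length. Immune cells in the culture are argued against by Ptprc and Lyz2, the higher of which was at 0.11 TPM with shETV4. A response to the hairpin or the virus may still account for it: with 1 hairpin against Etv4 and 1 shETV4 library, that cannot be told apart from an effect of lower Etv4.

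The GC trend itself may come from a composition bias between library preparations, which these values do not settle. Mitochondrially coded genes, transcribed outside the nucleus, had a median of -0.43 at percentile 64.3 among matched lists, as such a bias would give. Their GC-adjusted median was 0.38, however, so they lay less far down than the running trend at their GC content. Gene length as the whole cause is argued against by a rank correlation with GC content of at least 0.368 within each of 4 classes of transcript length. A difference in the cells that favours GC-rich transcripts of the nucleus was not tested.

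The genes Gphn, Cmss1, Tmtc2, Sspn, Cdk8, Camk1d and Lars2 were grouped by their ratio after their values were seen, so their shared direction was selected. They were 2.42-fold to 3.85-fold higher with shETV4. Tmtc2, Sspn and Cdk8 lay above the highest ratio of the 7 abundant unnamed loci, 3.15. Filip1l, also looked up and not in the group, went the other way, at 19.4 and 9.76 TPM. Levels in the group included Gphn at 2539 and 6855 TPM and Cmss1 at 2139 and 5177 TPM. Lars2, at 64.3 and 158 TPM, had been considered for the ribosomal RNA test and was set aside since its ratio was known; a gene model of the repeat, not analysed here, was considered next, before the search of transcripts.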
